A study of Mus musculus with 2 samples.

How the data were processed

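RNA of heart from male B6CASTF1/J mice aged 14 days was measured by stranded total RNA sequencing after depletion of ribosomal RNA, with spike-in RNAs added, in 2 libraries that the labels call biological replicates. Each library started from 300 ng of RNA. The labels name 3 males and give both replicates the same donor label; whether RNA of several animals was pooled is not stated, so each library was taken as 1 sample. Both libraries formed 1 group, so no groups could be compared, and no paired analysis was possible because there was only 1 group. The labels gave no sequencing batch or date for either library.

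The authors deposited, for each library, a gene table and a transcript table with the column names of RSEM and a transcript table with the column names of kallisto. The tool names used here come from those column names; the authors' tool versions are not given in the sources used here. Per the file headers, the RSEM-style tables hold expected counts, TPM, posterior mean TPM and the percent of the gene's TPM in each transcript. The deposited kallisto-style tables hold estimated counts and TPM per transcript. According to the authors' readme, reads were assigned to mm10 with the annotation M21. All 55536 gene identifiers and 141862 transcript identifiers were found in GENCODE M21, which gave symbols, gene types and coordinates. The tables also held 96 spike-ins and 26248 numbered identifiers that are not annotated genes. These numbered identifiers had 0.87 and 2.84 counts and were left out. Effective length was 99 bases below length in the RSEM-style tables and 332.1 and 336.1 bases below it in the kallisto-style tables, and 28639 transcripts had an effective length of 0 in the RSEM-style tables.

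Depth was 39334380 and 46391250 expected counts by the RSEM-style tables and 39318477 and 46118237 estimated counts by the kallisto-style tables. The main values were gene TPM and expected counts of the RSEM-style gene tables. Kallisto-style transcript values were summed per gene; 86 genes without a kallisto-style row were set to 0. A gene was called detected at 1 TPM or more in both libraries. For symbols with several identifiers (115 symbols) the identifiers were kept apart, and pairs and lists used the one with the highest mean TPM. Percentages of TPM were taken over all identifiers of a table. Errors are SDs over the 2 libraries.

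Before the data were examined, 60 pairs of related genes, 51 gene lists, 2 lists defined by symbol patterns (replication-dependent histone genes and ribosomal proteins), 30 genes for transcript usage, the tests and most alternatives were fixed. Of 607 distinct symbols in the lists, 604 were found in the tables; Ahsp, Cyr61 and Norad were not found under these symbols. The lists covered contractile, calcium, channel and metabolic genes, the cell cycle, transcription factors, heart chambers and the conduction system, imprinted genes, matrix, stress and signalling responses, the clock, noncoding RNAs, sex-linked genes, and markers of heart cell types, blood cells and neighbouring tissues. Genes named in the text were taken, without naming every one, from the members of the pairs, the 20 nuclear protein-coding and 5 mitochondrial genes with the highest TPM, the 4 highest detected members of each list and members below 1 TPM in both libraries, the 10 genes with the largest ratio between the libraries in each direction among genes with at least 100 counts in each, members of lists outside the central 95% of random lists, the transcript genes, the 10 genes with the largest ratio between the tables in each direction at 10 TPM or more, and the sex-linked genes.

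For each pair, the log2 ratio of TPM with a pseudocount of 0.1 was computed within each library and tested against 0 with the moderated test of limma (2-sided, intercept only, spread shared over the pairs; prior degrees of freedom 2.00, prior SD 0.18), with Benjamini-Hochberg adjustment over the 60 pairs and a threshold of 0.05. An exact permutation test of 2 values cannot pass 0.05. A ratio under 1 log2 unit was called small because the genes of a pair differ in length. Each list's level was its median TPM and the percentile of that median among 10000 random lists of the same size drawn from protein-coding genes at 1 TPM or more. A list was called detected when at least 3 members reached 1 TPM in both libraries. Agreement between the libraries was described by correlations across genes and by the common biological coefficient of variation of edgeR, with TMM factors and genes with at least 10 counts in each library; expected counts were rounded to whole numbers for edgeR, DESeq2 and the binomial test.

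Genes that differed between the libraries were called by a 2-sided exact binomial test on counts with TMM-scaled library sizes, over genes with at least 10 counts in each library or 20 in total, at a Benjamini-Hochberg adjusted p of 0.05 and an absolute log2 ratio of at least 1. Ratios have exact 95% intervals (Clopper-Pearson, from the binomial share). Where a library had 0 counts, the ratio was taken against a floor of 3 counts per library and is a lower bound. The difference of a list was the median log2 ratio of TPM of its members, compared with 10000 random lists matched on expression in 20 bins; these percentiles are descriptions and carry no p-value. A gene's shared sequence was the percent of its 31-base words that occur in the transcripts of another gene.

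The methods were tested on simulated data. For the binomial test, simulated counts held counting error only, and changes were placed only in genes with higher counts. The rates for this test therefore do not carry over to libraries that also vary biologically, or to genes with few counts. Among 16614 simulated genes for replicate 2 against replicate 1, the exact binomial test called 100% of the 100 genes changed 2-fold and 100% of the 100 genes changed 4-fold; 58% and 100% of them also passed the ratio threshold, and 3 unchanged genes were called, 0 of them past the ratio threshold. For the biological coefficient of variation of the 2 libraries, a simulated value of 0.1 over 16184 genes was estimated as 0.100. For the fixed gene pairs, limma called 40 of 40 true differences with the right sign and 1 of 20 pairs without one, among 60 simulated pairs. The simulated pairs were given smaller spreads between libraries than the widest real pairs, such as Nppa over Nppb (SD 1.31). For the gene lists between the 2 libraries, 20 of 20 moved lists were placed above the central range and 4 of 80 lists that were not moved lay outside it, over 25780 genes. Members of the simulated lists varied independently, which members of the real lists need not do.

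The alternatives, each changed alone, were kallisto-style values, pseudocounts of 0.01 and 1, counts not divided by length, posterior mean TPM, other detection thresholds, TPM rescaled without mitochondrial genes and spike-ins, the mean of log2 TPM in place of the median, DESeq2 size factors, total counts or spike-in totals in place of TMM, other count filters, the edgeR exact test with an assumed coefficient of variation of 0.1 or 0.2, other random lists, and each library left out. Alternatives chosen after seeing the data were TPM summed over protein-coding transcripts only, for the pairs, and counts scaled by TMM library sizes, for the lists between libraries. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. Allele-specific expression was not analysed here, because the tables assign reads to a single reference genome.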

Results

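Total RNA from the heart of male B6CASTF1/J mice, the first-generation hybrid of the C57BL/6J and CAST/EiJ inbred strains, was sequenced at 14 days of age in 2 biological replicates that formed a single group. The RNA was depleted of ribosomal RNA before stranded libraries were made, and spike-in RNAs of known sequence were added. The gene tables held 39334380 expected counts for replicate 1 and 46391250 for replicate 2. Spike-ins took 0.517% and 0.531% of these counts, and phiX, the usual sequencing control, took 0 counts in both libraries. At this depth a gene of 2 kb at 1 TPM, an abundance scaled for gene length and library size, was backed by 61.2 and 73.3 counts. Unless another unit is named, levels are TPM as mean ± SD over the 2 libraries (n = 2). A total of 12487 genes reached 1 TPM in both libraries, of which 11421 were protein-coding, and 797 genes reached it in 1 library only.

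The sex given by the labels was checked first. The Y-linked genes Eif2s3y, a translation initiation factor, and Ddx3y, an RNA helicase, stood at 30.2 ± 0.304 and 24.0 ± 0.403 TPM, followed by the histone demethylases Uty at 9.93 ± 0.339 and Kdm5d at 5.27 ± 0.0849. The Y-linked Zfy1 and Usp9y had 0 counts in both libraries. Xist (chromosome X, 103460366 to 103483254, mm10), the RNA that coats the inactive X chromosome, had 6 and 2 counts, and Tsix, its antisense partner, was at 0.065 TPM. The median of the Y-linked list was 7.60 ± 0.212 TPM, and that of the X inactivation pair was 0.035 TPM in each library. No library stood out against its label.

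Transcripts encoded by the mitochondrial genome took 28.5 ± 0.651% of all TPM. The ribosomal RNAs mt-Rnr2 (mitochondrial genome, 1094 to 2675) and mt-Rnr1 alone took 16.6 ± 0.290%, and the mitochondrial protein-coding genes took 11.9 ± 0.361%, led by the cytochrome c oxidase subunit mt-Co1 at 31836 ± 243 TPM. The oxidase subunit mt-Co3 (14367 ± 519 TPM) and mt-Cytb (13404 ± 297 TPM), a subunit of the bc1 complex, came next. Nuclear protein-coding genes took 42.3 ± 0.164% of TPM and 64.7% of expected counts. Genes annotated as miscellaneous RNA, chiefly the short 7SL and 7SK RNAs, took 17.0 ± 0.715% of TPM but 2.74% of expected counts. By the kallisto-style table they took only 0.00238% of TPM. Gm28661, Gm29216, Gm10925 and Gm28437, pseudogenes side by side on chromosome 1 (24613189 to 24616197) that copy mitochondrial sequence, together took 5.78 ± 0.196%. Of the 31-base words of Gm28661, 100% also occurred in mitochondrial transcripts, so the origin of the reads assigned to these copies is uncertain.

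Among nuclear protein-coding genes, the highest were those of blood and of the contractile apparatus. The beta-globin gene Hbb-bs (chromosome 7, 103826534 to 103828096) was at 10488 ± 402 TPM and Myh6 (chromosome 14, 54941921 to 54966927), the alpha heavy chain of cardiac myosin, at 10130.3 ± 863. The alpha-globin copies Hba-a1 and Hba-a2 followed at 7891 ± 59.7 and 7301 ± 141; their coding sequences are near identical, so the division between them is uncertain. Hemoglobin genes took 2.69 ± 0.0659% of TPM, or 4.54% by the kallisto-style table. Next came Actc1 (chromosome 2, 114047282 to 114053548), cardiac actin, at 7250.3 ± 142, Myl2 (chromosome 5, 122100951 to 122113472), the ventricular regulatory light chain, at 7132 ± 117, and the oxygen carrier Mb (chromosome 15, 77015487 to 77050670) at 5554 ± 142. Further down were the light chain Myl3 (5004 ± 52.1), tropomyosin Tpm1 (4771 ± 92.2), the calcium pump Atp2a2 (3912 ± 88.5), the ATP synthase subunit Atp5b (3506 ± 80.2) and the troponins Tnnt2 (3373 ± 159), Tnni3 (3040.4 ± 61.7) and Tnnc1 (2017 ± 17.5). The rest of the 20 highest were Fabp3, Pln, Slc25a4, Cox6b1, Cox4i1 and Gapdh, between 2619 ± 39.2 (Fabp3, a fatty acid binding protein) and 1710.2 ± 12.8 (Gapdh). Together these 20 genes took 22.1 ± 0.384% of the TPM of nuclear protein-coding genes.

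The contractile genes were compared as fixed pairs of related genes, each taken within a library, so that the value is the log2 ratio of the first gene over the second. All 15 contractile pairs passed the limma moderated test with the first gene higher. Myh6 exceeded Myh7 (901 ± 113 TPM), the beta heavy chain, by 3.49 ± 0.06 log2 units, which is 11.3-fold (adjusted p 0.000239, both libraries). Most Myh7 TPM lay in a short intron-retaining transcript, and with protein-coding transcripts alone, an alternative chosen after seeing the data, the ratio was 6.10, against 2.19 with kallisto-style values. Tnni3 exceeded Tnni1, the slow skeletal form used before birth, by 7.82 ± 0.18, or 226-fold (Tnni1 13.4 ± 1.91 TPM). That ratio was 6.83 with protein-coding transcripts alone and 7.34 with kallisto-style values. Tnnt2 exceeded Tnnt1 by 7.90 ± 0.04, and Actc1 exceeded the skeletal actin Acta1 (131 ± 22.3 TPM) by 5.80 ± 0.22, or 55.6-fold, and the smooth muscle actin Acta2 (162 ± 27.6 TPM) by 5.49 ± 0.22. Casq2 exceeded Casq1, the skeletal calcium-storage protein, by 6.47 ± 0.11. The skeletal forms Tnnt3, Tnnc2, Ryr1, Atp2a1 and Actn3 were between 0.01 TPM (Ryr1) and 0.37 TPM (Tnnt3).

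Pairs with an atrial gene had a wide spread between the libraries. Myl2 over Myl7, the atrial regulatory light chain, was 4.23 in replicate 1 and 5.82 in replicate 2 (mean 5.02 ± 1.13, adjusted p 0.00244). Myl3 over Myl4, the atrial essential light chain, was 3.93 and 5.43 (mean 4.68 ± 1.07, adjusted p 0.00252). Nppa over Nppb, both natriuretic peptide genes and counted with the regulators, was 3.85 and 2.00 (mean 2.92 ± 1.31, adjusted p 0.0140), with Nppb at 59.4 ± 1.72 TPM. These p-values come from limma, which shares the spread over all 60 pairs (prior SD 0.18). That shared spread is narrower than the spread of these pairs, so their p-values lean on the other pairs. They cover only the spread between these samples, part of which may be technical.

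In metabolism, 18 of 19 pairs had the first gene higher past the test. The insulin-responsive glucose transporter Slc2a4 (89.5 ± 7.02 TPM) exceeded the basal transporter Slc2a1 (2.93 ± 0.523 TPM) by 4.89 ± 0.14, or 29.7-fold (adjusted p 0.000166). The muscle form of carnitine palmitoyltransferase, Cpt1b (251 ± 9.82 TPM), exceeded the liver form Cpt1a (38.1 ± 7.25 TPM) by 2.73 ± 0.22 (adjusted p 0.000561). The heart form of lactate dehydrogenase, Ldhb, exceeded Ldha by 1.44 ± 0.08 (adjusted p 0.00154; 833 against 308 TPM). The muscle forms of other enzymes were also higher: Ckm over Ckb by 5.11 ± 0.03, Eno3 over Eno1 by 3.46, Pfkm over Pfkl by 2.84 and over Pfkp by 3.36, Pgam2 over Pgam1 by 2.74, Cox6a2 over Cox6a1 by 2.09 and Cox8b over Cox8a by 1.90. The adenine nucleotide carrier Slc25a4 exceeded Slc25a5 by 2.90. Of the regulators, Pdk4 exceeded Pdk2 by 1.64, Ppara exceeded Pparg by 1.80, Ppargc1a exceeded Ppargc1b by 1.41 and Esrra exceeded Esrrg by 1.90. The exception was the uncoupling protein pair: Ucp3 (26.6 ± 5.56 TPM) was below Ucp2 (362 ± 58.8 TPM), with a log2 ratio of -3.77 ± 0.54, or 13.6-fold (adjusted p 0.00102). The ratios of Hk2 over Hk1 (0.65 ± 0.04) and Cox7a1 over Cox7a2 (0.91) passed but were small, and by the kallisto-style table they were 0.18 and -0.066, neither past the threshold.

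In the channels, pumps and receptors class, 11 of 12 pairs had the first gene higher. The ventricular gap junction gene Gja1 (173 ± 7.95 TPM) exceeded Gja5 by 4.83 ± 0.43 and Gjc1 by 3.39. The calcium channel Cacna1c (80.3 ± 0.771 TPM) exceeded Cacna1d by 5.40 ± 0.32. Hcn2 exceeded the pacemaker channel Hcn4 (1.89 ± 0.0283 TPM) by 2.94 ± 0.11, and Cacna1g exceeded Cacna1h by 2.31. The thyroid hormone receptor Thra (54.1 ± 1.44 TPM) exceeded Thrb (8.49 ± 1.49 TPM) by 2.67 ± 0.21. Kcnd2 over Kcnd3 (0.97 ± 0.44, adjusted p 0.0206) passed with a small ratio. Dio2 passed over Dio3, though both deiodinases were under 1 TPM (0.385 and 0.02). Kcnj2 and Kcnj12 (14.2 and 12.5 TPM) did not differ detectably (0.17 ± 0.06, adjusted p 0.213).

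The last class held growth factors, imprinted genes, matrix genes and other regulators, and 11 of its 14 pairs passed. Igf2 (chromosome 7, 142650766 to 142666816; 159 ± 22.3 TPM), a paternally expressed growth factor, was 12.8-fold above Igf1 (chromosome 10, 87858265 to 87937042), a log2 ratio of Igf1 over Igf2 of -3.68 ± 0.03 (adjusted p 0.000216). H19 (chromosome 7, 142575529 to 142578143; 63.1 ± 7.92 TPM), the maternally expressed RNA of the same locus, was below Igf2, with a ratio of -1.33 ± 0.02 (adjusted p 0.00167), and Meg3 exceeded Dlk1 by 3.03 ± 0.48. Col1a1 (214 ± 27.3 TPM) was below Col3a1 (483 ± 53.3 TPM), both fibrillar collagens, at -1.18 ± 0.02 (adjusted p 0.00224). The nuclear lamina gene Lmna exceeded Lmnb1 by 2.92 ± 0.52, Igf2bp2 exceeded Igf2bp3 by 3.08, Ccnd2 exceeded Ccnd1 by 1.76, Mef2a exceeded Mef2c by 1.18, Lamb2 exceeded Lamb1 by 1.08 and Des exceeded Vim by 0.92. The ratios of Gata4 over Gata6 (-0.058, adjusted p 0.692; 44.6 and 46.5 TPM), Vegfa over Vegfb (-0.31, adjusted p 0.116) and Rbm20 over Rbm24 (0.041, adjusted p 0.738) did not pass. With counts not divided by gene length, Lamb2 over Lamb1 (0.35) and Cox7a1 over Cox7a2 (0.13) no longer passed, while Kcnj2 over Kcnj12 (1.46), Rbm20 over Rbm24 (0.65) and, with the sign changed, Vegfa over Vegfb (0.50) did. With protein-coding transcripts only, Vegfa over Vegfb passed at -1.03 and Hk2 over Hk1 (0.17) no longer passed. Over all 60 pairs, 56 passed, 51 of them by 1 log2 unit or more, and 58 had the same sign in both libraries.

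**Figure D1:**
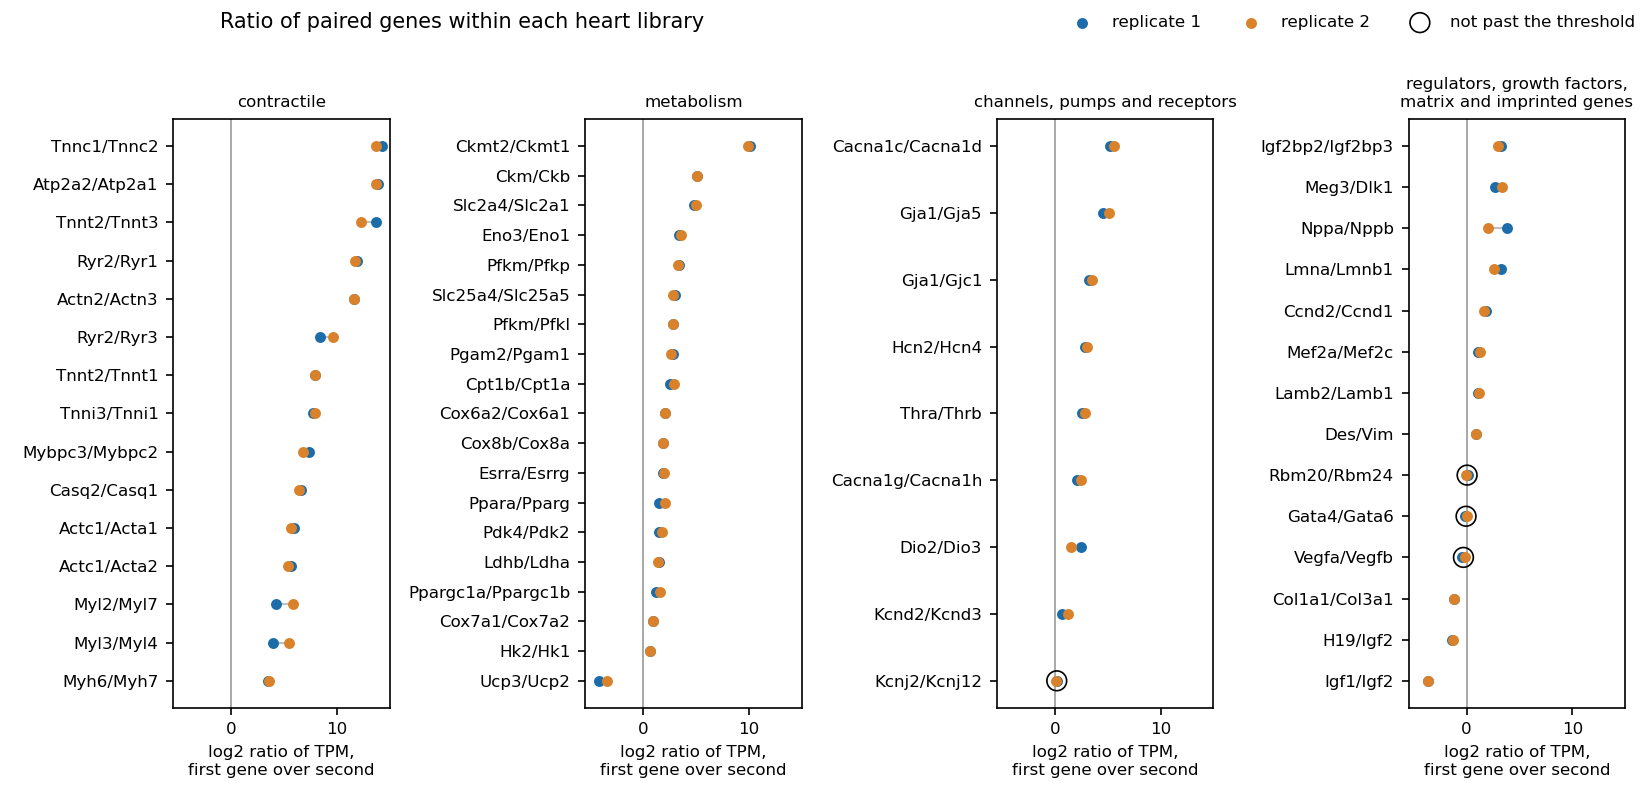
Log2 ratio of TPM (first gene over second gene) for fixed pairs by class (not every pair is drawn), with one point per library, a line that joins both libraries and circles around pairs not past the threshold. The first gene is the higher in most pairs, and the widest gaps between libraries include Nppa/Nppb, Myl2/Myl7 and Myl3/Myl4.

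Gene lists fixed before the data were examined described the level of each program by its median TPM, with its percentile among 10000 random lists of expressed protein-coding genes as a description. The sarcomere list had a median of 704 ± 8.50 TPM and calcium handling 149.8 ± 3.65, with the calcium store protein Casq2 at 458 ± 11.3 and the release channel Ryr2 at 393 ± 9.99. Nuclear oxidative phosphorylation genes stood at 691 ± 17.1, with Atp5a1 at 1689 ± 24.7, mitochondrially encoded proteins at 7883 ± 329, the tricarboxylic acid cycle at 339 ± 3.78, fatty acid oxidation at 329.9 ± 7.85 (Hadhb 763 ± 19.4, Acaa2 759 ± 53.2, Cd36 704 ± 71.9) and glycolysis at 257 ± 1.55 (Aldoa 1181 ± 17.5). All of these lists were at the percentile 100 in both libraries. Ketone body use was at 49.7 ± 4.56, led by Oxct1 at 227 ± 13.4. Perinatal contractile and stress genes were at 84.6 ± 2.54, cardiac transcription factors at 36.7 ± 1.61, with Mef2a at 64.3 ± 4.84 and Tead1 at 61.9 ± 1.48, and ion channels and gap junctions at 15.7 ± 0.410, with the potassium channel subunit Kcne1 at 96.0 ± 1.56. Extracellular matrix genes were at 96.4 ± 1.17, with Sparc at 558 ± 12.3 and Col4a1 at 451 ± 16.4, and ribosomal proteins at 204 ± 6.62, with Rpl41 at 771 ± 33.5. Hand1 had 0 counts in both libraries and Isl1, a progenitor factor, was at 0.08 TPM.

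Cell cycle lists lay at different levels. The S phase list was at 3.53 TPM in replicate 1 and 5.72 in replicate 2 (percentiles 0.385 and 6.86 among random lists), the list of G2 and M phase at 2.46 and 3.57 (0 and 0.11), and histone genes at 16.6 and 28.6 (99.7 and 100). Pcna, the DNA polymerase clamp, was at 20.9 ± 3.92 TPM, Top2a at 8.34 and 13.99, and Mki67 at 5.77 and 7.62. The library with the higher values was in each case the one with more T cell and thymus counts. With 2 libraries, this cannot be told apart from any other difference between them. Cell cycle inhibitors were at 10.3 ± 0.499 (percentiles 51.6 and 56.6), with Ccng1 at 125 and the kinase inhibitor Cdkn1a at 52.3 TPM.

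Marker lists covered the cell types of a whole heart and the tissues beside it. Cardiomyocyte markers had a median of 2561 ± 80.0 TPM, erythroid markers 684 ± 37.1 (1586 by the kallisto-style table), endothelial markers 74.2 ± 4.41 (Fabp4 436 ± 63.8, Cdh5 99.2 ± 4.71), fibroblast markers 70.4 ± 8.17 (Dcn 168 ± 13.4), pericyte markers 16.4 ± 0.993 (Rgs5 156 ± 3.91) and smooth muscle markers 15.3 ± 0.0212 (Smtn 77.7 ± 3.97). Endocardial (8.04 ± 1.17; Vwf 40.3 ± 5.88), lymphatic endothelial (7.14 ± 0.516; Prox1 16.2), epicardial (4.58 ± 1.27; Msln 12.6) and macrophage markers (4.61 ± 0.322; C1qb 16.3 ± 2.86, C1qa 15.5 ± 2.11) were detected at lower levels. Mast cell and granulocyte markers were at 1.11 TPM (Kit 2.29), platelet markers at 1.41 (Pf4 14.3 ± 1.87) and markers of Schwann cells and neurons at 0.435 (Mbp 1.98). Atrial genes were at 22.3 and 10.2 TPM, ventricular genes at 15.6 and 11.2 (Fhl2 745 ± 124, Lbh 130.2 ± 0.191) and conduction system genes at 2.01 ± 0.198 (Tbx3 6.26). Brown adipocyte markers were at 17.8 and 11.5 TPM, a list whose Cox8b and Ppargc1a the heart also expresses, and adipocyte markers at 3.74 and 2.04 (Cfd 10.09 and 5.83). T cell markers were at 0.275 and 6.64 TPM and thymus markers at 0.015 and 3.94, so that neither list was detected in both libraries.

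Other tissues gave little signal. Lung epithelium markers were at 0.035 TPM, with 0 counts of the surfactant genes Sftpa1, Sftpb and Sftpd, liver markers at 0.0375, with 1 and 10 counts of Alb, B cell markers at 0.403 ± 0.0177 and cartilage markers at 0.33. The skeletal muscle list was at 0.16 TPM, and its member Myh2 had 0 counts. The highest members of this list, Ckm at 1687 ± 14.2 and Acta1, are also heart genes. Its members Tnni2 and Mylpf also reached 1 TPM in both libraries. In all, 43 of the 53 lists had a median of 1 TPM or more in both libraries.

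**Figure D2:**
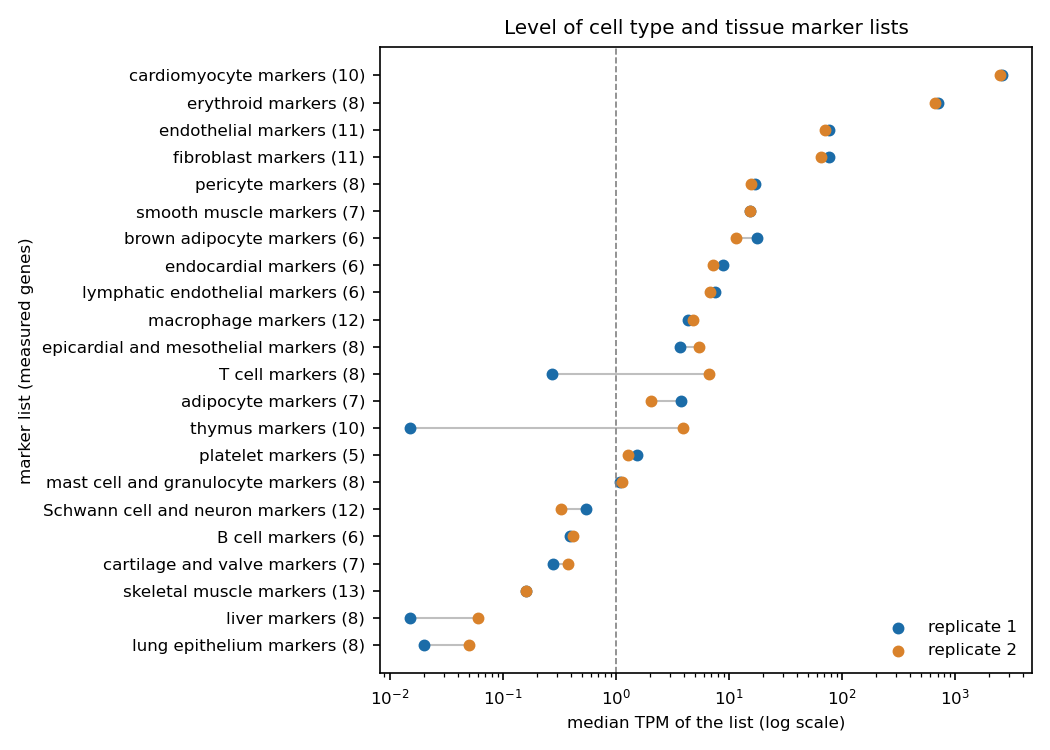
Median TPM (log axis) of the cell type and tissue marker lists, one point per library. Most lists have nearly the same median in both libraries, while T cell and thymus markers lie far apart.

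The libraries agreed closely over most genes. Across the 12487 genes at 1 TPM or more, which are not independent replicates, log2 TPM had a Pearson correlation of 0.990 and a Spearman correlation of 0.987, and 98.9% of genes lay within 2-fold. The biological coefficient of variation by edgeR was 0.117 over 15950 genes. The median log2 ratio of replicate 2 over replicate 1 was 0.017. The 28 spike-ins with at least 100 counts in each library had a median absolute log2 ratio of 0.06, against 0.10 for genes of like counts. The SD of the log2 ratios of these spike-ins was 0.104, and their median counting SD was 0.0539. These are unlike measures, because spike-ins with few counts, such as ERCC-00078 (100 and 128 counts), weigh most on the former. Their difference therefore does not show a spread beyond counting error.

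**Figure D3:**
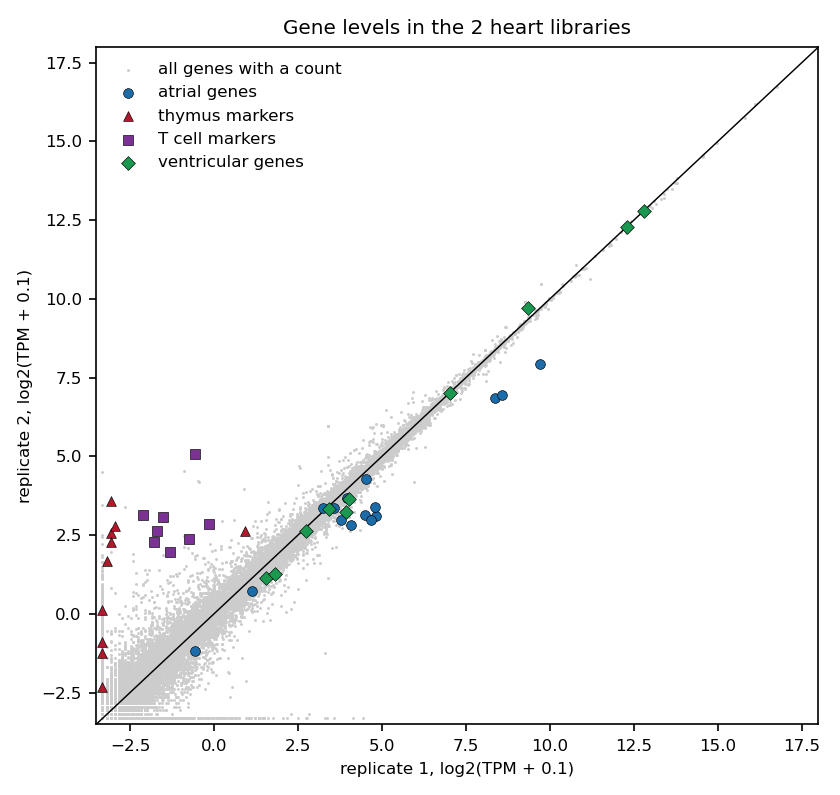
Log2 of TPM plus 0.1 in replicate 2 against replicate 1 for every gene with a count, with atrial genes, ventricular genes, T cell markers and thymus markers in colour. Most genes at 1 TPM or more lie near the diagonal (Pearson 0.990), while T cell and thymus markers lie above it and most atrial genes below it.

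Among genes with at least 100 counts in each library, the largest differences included leukocyte genes, which were higher in replicate 2, and atrial genes, which were higher in replicate 1. This test compares these libraries, not conditions. Of 16611 genes tested by an exact binomial test on counts, 537 (3.23%) passed with a ratio of at least 2-fold, 413 higher and 124 lower in replicate 2, and 3650 passed at any ratio. The edgeR exact test gave 313 higher and 76 lower with an assumed coefficient of variation of 0.1, and 193 higher and 37 lower with 0.2. Far fewer genes passed the binomial test in either direction when at least 100 counts were required in each library. Intervals are exact and, like floors, cover counting error only. The highest ratio of replicate 2 over replicate 1 among genes with at least 100 counts in each library was that of Ptprc (chromosome 1, 138062861 to 138175708), the pan-leukocyte phosphatase CD45, with 189 and 1053 counts, a ratio of 4.59 (95% interval 3.93 to 5.39). Nr4a1 (chromosome 15, 101254269 to 101274795), an immediate early nuclear receptor, followed at 4.58 (4.12 to 5.11), then the leukocyte genes Coro1a at 3.78 (3.12 to 4.61) and Dock2 at 3.65 (2.95 to 4.55), and Nr4a3 at 3.41 (2.94 to 3.97). Gm21887, Arhgap45, the leukocyte integrin Itgb2, Glcci1 and the histone gene Hist1h3h completed the 10 highest, down to 2.48 (2.19 to 2.81) for Hist1h3h. In the other direction, Nppa (chromosome 4, 148000722 to 148002079) had 19713 and 6797 counts, 840.9 and 242 TPM, and was 3.52-fold (3.43 to 3.62) higher in replicate 1. Lars2, a mitochondrial aminoacyl-tRNA synthetase, was 3.58-fold (3.42 to 3.75) higher there, the growth factor Bmp10 3.41-fold (3.20 to 3.63), Mybphl 3.32-fold (2.92 to 3.77), Myl7 3.14-fold (2.99 to 3.29) and Myl4 2.93-fold (2.80 to 3.06). The remaining genes of the 10 lowest were Fgf12, Sln, Pck1 and Sbk3.

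Among gene lists, T cell markers had a median log2 ratio of 4.20, or 5.20 with genes near 0 counts at their bounds, and all 8 members were higher in replicate 2 past the exact test. Their summed counts were 89 and 3459, a ratio of 32.0 (25.9 to 40.0). Cd8a, a coreceptor of T cells, had 9 and 841 counts, and Trbc2, a constant region of the T cell receptor, 0.57 and 33.8 TPM. Thymus markers had a median log2 ratio of 4.16, or 5.43 at the bounds, and summed counts of 96 and 4807, a ratio of 41.2 (33.7 to 51.0). Rag1 (chromosome 2, 101638282 to 101649501), a recombinase active in developing lymphocytes, had 4 and 2855 counts, a ratio of 588 (229 to 2159). Dntt, which adds bases at receptor gene joints, had 1 and 460 counts, a ratio of 379 (67.7 to 14995). Against a floor of 3 counts per library, Rag2 was at least 22.5-fold and Psmb11, a proteasome subunit of the thymic cortex, at least 18.4-fold higher in replicate 2. B cell markers, with a median log2 ratio of 0.28, and erythroid markers, at -0.059, lay inside the central 95% of random lists, though all 6 B cell markers were higher in replicate 2, with 227 and 502 summed counts, a ratio of 1.82 (1.55 to 2.14), and 1 of them passed the exact test.

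Atrial genes had a median log2 ratio of -1.25, and 14 of 15 were lower in replicate 2, 8 of them past the exact test with at least a 2-fold ratio. Their summed counts were 49821 and 23943, and were 2.53-fold (2.49 to 2.57) higher in replicate 1. Upk3b was the exception, at 0.12, and the atrial channel genes Kcnj3 and Kcnj5 differed less, at -0.26 and -0.25. The sarcomere list, which holds Myl4 and Myl7, was at -0.04 and cardiomyocyte markers were at -0.04, both inside the central range. The ventricular list, at -0.11, was outside it on the same side as the atrial list, but inside by the kallisto-style table.

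In all, 13 lists lay outside on the higher side in replicate 2 and 13 on the lower side. If list members varied independently, 2.65 of the 53 lists would lie outside by chance. The lists hold related genes and some share members, so 2.65 is not a firm reference for them. Among the higher ones were histone genes (0.82; 61 members higher), G2 and M phase (0.41), S phase (0.40), mast cell and granulocyte markers (0.43), epicardial markers (0.32), interferon response (0.32), heat shock and unfolded protein response (0.28), macrophage markers (0.25), immediate early genes (0.22) and, with small shifts, small noncoding RNA genes (0.10) and ribosomal proteins (0.05). Top2a was 1.79-fold (1.64 to 1.95) higher in replicate 2. Among the lower ones were adipocyte markers (-0.65), endocardial markers (-0.32), smooth muscle markers (-0.30), fibroblast markers (-0.23), brown adipocyte markers (-0.23), conduction system genes (-0.17), perinatal contractile and stress genes (-0.17), extracellular matrix (-0.14), endothelial markers (-0.11), mitochondrially encoded proteins (-0.10) and fatty acid oxidation (-0.09). The perinatal contractile and stress list shares Nppa, Myl4 and Mybphl with the atrial list, and these were its 3 members called lower. Of the adipocyte markers, 6 were lower and 1 higher in replicate 2, and only the higher one passed the exact test with a 2-fold ratio. Ucp1, the uncoupling protein of brown fat, had 459 and 18 counts and was 30.96-fold (19.4 to 52.7) higher in replicate 1. Plin1, which coats lipid droplets, was at 4.19 and 2.04 TPM. The summed counts of some of these lists did not follow the median: smooth muscle markers had 15627 and 20854 counts, a ratio of 1.10 (1.08 to 1.12), with no member called lower, brown adipocyte markers a ratio of 1.01 (0.986 to 1.03) and interferon response genes a ratio of 1.01 (0.956 to 1.06), with a median of 0.925 and 0.740 TPM. With members at 1 TPM or more only, the mast cell and granulocyte list was at -0.066, and the brown adipocyte, epicardial and interferon lists lay inside the central range. For brown adipocytes this kept only Cox8b, Ppargc1a and Cidea and left out Ucp1, so it does not bear on the Ucp1 difference. The summed counts of that list include Cox8b and Ppargc1a, which the heart also expresses. By the kallisto-style table, the macrophage and mitochondrially encoded protein lists lay inside it, while the small noncoding RNA list, with a median of 0 TPM there, could not be compared, and with scaled counts in place of TPM, chosen after seeing the data, the macrophage, mast cell and small noncoding RNA lists lay inside it. Other lists came to lie outside on the lower side: ion channels (-0.12), clock genes (-0.15), imprinted genes (-0.083), platelet markers (-0.45) and markers of Schwann cells and neurons (-0.33) with scaled counts, ion channels (-0.082) and Schwann cells and neurons (-0.28) by the kallisto-style table, and cartilage markers (-0.58) with members at 1 TPM or more.

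**Figure D4:**
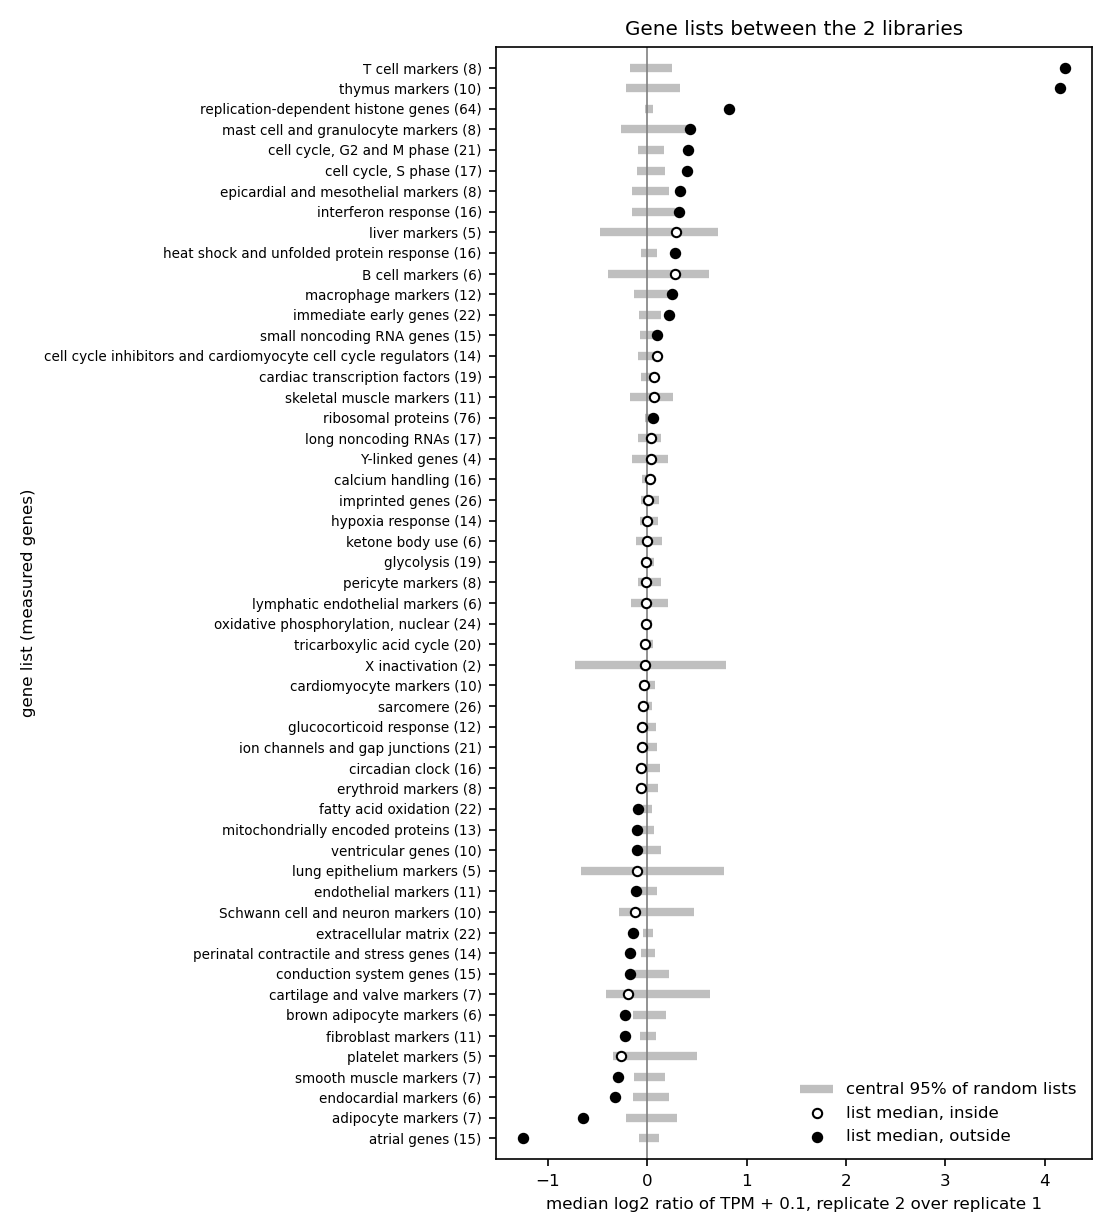
Median log2 ratio of TPM (replicate 2 over replicate 1) of the 53 gene lists, with bars for the central 95% of 10000 random lists of like expression. T cell (4.20) and thymus markers (4.16) lie far to the right, and atrial genes (-1.25) farthest to the left.

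Transcript usage was described for 30 fixed genes as each transcript's share of the gene's TPM. In 17 of them a single transcript held most of the TPM, and in 29 the leading transcript was the same in both libraries. Actc1-201 held 99.98 ± 0.0139% of Actc1 and Tpm1-205 96.9 ± 0.146% of Tpm1. Ryr2-201 held 80.5 ± 1.22% and Atp2a2-202 75.7 ± 0.340%, with Atp2a2-201 at 22.7 ± 0.0389%. The largest shares of titin TPM were those of Ttn-201 (38.3 ± 0.913%) and the short Ttn-215 (30.5 ± 0.135%, or 19.5% by the kallisto-style table). Ttn-218 followed at 13.1%. In counts, which are not divided by length, Ttn-215 had 20804 and 24041, against 1.06e+06 and 1.17e+06 for the far longer Ttn-201. Myh6-201 held 42.8 ± 0.922% of Myh6, Mef2a-208 60.4 ± 1.23% of Mef2a and Ldb3-203 61.1 ± 2.11% of Ldb3, a Z-disc gene. In Myh7, the intron-retaining Myh7-206 of 595 bases held 83.7 ± 0.241% of TPM and the coding Myh7-201 16.3 ± 0.242%. In counts, which are not divided by length, the coding Myh7-201 was the higher, with 29206 and 29926 against 12493 and 12484. By share of TPM, the leading transcripts of Cacna1c and Igf2 were not protein-coding either. The short Cacna1c-218 had 822 and 998 counts, against 5553 and 6373 for the coding Cacna1c-207. By the kallisto-style table another transcript, Igf2-209, led Igf2 (38.4%). Neat1 and Malat1 are noncoding genes, so their leading transcripts could not be protein-coding. In Bin1, which shapes the transverse tubules, Bin1-205 led in replicate 1 (43.97%) and Bin1-202 in replicate 2 (37.7%), while by the kallisto-style table Bin1-202 led in replicate 1 (38.5% against 26.2%) and Bin1-205 in replicate 2 (35.5% against 27.1%).

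By mean shares over the libraries, the kallisto-style table gave the same leading transcript for 22 of the 30 genes and another for 8. It gave Tnnt2-209 49.9% of the cardiac troponin T gene, where the RSEM-style table gave Tnnt2-211 56.7 ± 0.802%. For pyruvate kinase, Pkm-202 held 52.4 ± 2.29% by the RSEM-style table, while the kallisto-style table gave Pkm-201 and Pkm-202 nearly equal mean shares (45.1% and 44.2%), with Pkm-201 ahead in replicate 1 and Pkm-202 in replicate 2. Ldha-202 held 98.0 ± 0.933% by the RSEM-style and 33.4% by the kallisto-style table, and Malat1-201 held 38.9 ± 1.22% and 99.9%. The leading share moved by more than the SD between the libraries with the kallisto-style table for 25 of the 30 genes, so isoform shares depend on the quantifier for most of them.

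Both quantifications were compared gene by gene. The signal recognition particle genes Rn7s1 and Rn7s2, which share all their 31-base words, stood at 72987 ± 3658 TPM each by the RSEM-style table and at 0.127 by the kallisto-style table. The 7SK gene Rn7sk stood at 24192 ± 165 and 1.41 TPM, the mitochondrial copy Gm10925 at 11619 ± 27.8 and 0.0708, and Rmrp, an RNA of the mitochondrial RNA processing ribonuclease, at 1812 ± 99.7 and 0. A second identifier of Rmrp stood at 1368 ± 72.8 and 0 TPM. The ATP synthase gene mt-Atp8 (204 bases) stood at 3461 ± 181 and 0, with 7.47% of its 31-base words in another gene. In the other direction, the mitochondrial copy Gm28439 was at 0 TPM by the RSEM-style and at 799.6 ± 279.5 by the kallisto-style table. A second identifier of Nnt (chromosome 13, 119335528 to 119408952), a mitochondrial transhydrogenase, was at 0 and 113 ± 5.50. All its 31-base words occurred under another gene identifier. Next came Gm47283 (35.9 by kallisto), AW822252 (33.6) and Gm42860 (25.3). Across the 6591 genes at 10 TPM or more by either table, which are not independent, the Spearman correlation was 0.836; 217 genes were over 2-fold higher by kallisto and 231 by RSEM, together 6.80%. Of 6205 protein-coding genes, 3.17% were over 2-fold apart.

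**Figure D5:**
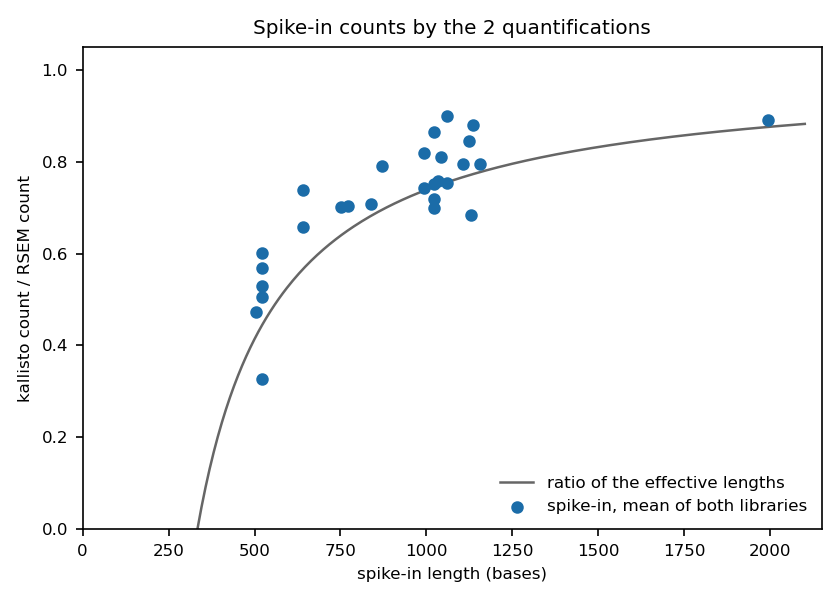
Ratio of kallisto-style to RSEM-style counts against length in bases for 28 spike-ins, mean of both libraries, with the ratio of the effective lengths of both tables as a line. The ratio runs from 0.328 to 0.899 over 505 to 1994 bases.

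The spike-ins were compared between the tables as well. Over the 28 spike-ins the ratio of kallisto-style over RSEM-style counts ran from 0.328 to 0.899, and it had a Spearman correlation of 0.796 with length over spike-ins of 505 to 1994 bases. The ratio of the effective lengths of both tables predicted it with a median absolute difference of 0.0623. The ratio of TPM, which takes effective length into account, ran from 0.721 to 1.32, so that no spike-in was over 2-fold apart in TPM, and no spike-in shorter than 505 bases was compared.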

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

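Protein-coding transcripts for the pairs and scaled counts for the lists were alternatives chosen after seeing the data; the other alternatives were planned. Of the 60 pairs, 53 passed with kallisto-style values, 57 with counts not divided by length and 56 with posterior mean TPM or either other pseudocount, against 56; 54 of 58 passed with protein-coding transcripts. The pairs that changed sign had ratios under 1 log2 unit: Cox7a1 over Cox7a2 was -0.066 with kallisto-style values; Gata4 over Gata6 was 0.016 with kallisto-style values and 0.097 with protein-coding transcripts, and -0.18 to 0.067 when a library was left out; Vegfa over Vegfb was 0.50 with counts not divided by length; Rbm20 over Rbm24 was -0.15 with protein-coding transcripts, and -0.018 to 0.099 when a library was left out. The mast cell and granulocyte list was -0.066 with members at 1 TPM or more. At 10 TPM, 5760 genes were detected. With kallisto-style values, the median TPM of 37 of the 53 lists and the leading share of 25 of the 30 transcript genes moved by more than the SD between the libraries. Mitochondrially encoded genes took 25.7% of counts and 34.3% of kallisto-style TPM. The Pearson correlation was 0.988 without a filter, 0.992 with a pseudocount of 1 and 0.988 with kallisto-style values. The biological coefficient of variation was 0.145 without a filter and 0.0880 at 100 counts. At 100 counts in each library, 11416 genes were tested, and 33 were higher and 18 lower in replicate 2. This filter also leaves out genes near 0 counts in 1 library, such as Rag1 and Cd8a. The edgeR exact test gave 76 lower with an assumed coefficient of variation of 0.1, and 193 higher and 37 lower with 0.2. With members at 1 TPM or more, 8 lists were higher in replicate 2. Between the tables, the Spearman correlation was 0.894 for genes at 1 TPM or more and 0.936 for protein-coding genes, of which 3.17% were over 2-fold apart. The cause of these changes was not tested. The T cell, thymus and atrial lists stayed outside the central range in their direction under every alternative that gave a value: T cell markers from 3.31 (kallisto-style) to 4.37 (scaled counts), thymus markers from 3.39 to 4.95, and atrial genes from -0.99 to -1.29. Too few T cell and thymus members reached 1 TPM in both libraries for a value there. Over the pairs and the settings with a test, 404 values were the same in direction and side of the threshold, 5 changed sign, 5 dropped out and 3 came in; with a library left out there was no test, and 118 values kept their sign and 2 did not. Depth limits genes near 0 counts, for which only a lower bound of a ratio can be given.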

Other observations

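The tests of sequence shared with other genes were fixed before their result was seen; the other tests of an explanation were chosen only after the result was seen.

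Imprinted genes had a median of 9.53 ± 0.573 TPM (mean ± SD, n = 2). Gnas, which encodes the stimulatory G protein subunit, was the highest at 561 ± 8.69 TPM, followed by Igf2 at 159 ± 22.3, the adaptor gene Grb10 at 65.1 ± 2.20 and H19 at 63.1 ± 7.92. Kcnq1ot1 (0.54 TPM), Peg10 (0.645) and Phlda2 (0.05) stayed below 1 TPM in both libraries. Long noncoding RNAs had a median of 10.6 ± 0.0495 TPM, with Malat1 at 1953 ± 268, Neat1, the scaffold of paraspeckles, at 67.0 ± 0.785 and Mhrt, transcribed antisense to Myh7, at 37.1 ± 0.304. Small noncoding RNA genes were at 276 ± 21.4 TPM by the RSEM-style table and at 0 by the kallisto-style table.

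Circadian clock genes had a median of 9.46 ± 0.806 TPM, with Per1 at 38.5 ± 5.12 and Tef at 35.1 ± 9.45, and glucocorticoid response genes 56.4 ± 0.997, with the pyruvate dehydrogenase kinase Pdk4 at 399 ± 36.7, the metallothionein Mt1 at 176.5 ± 24.7 and Tsc22d3 at 109 ± 0.827. Hypoxia response genes were at 17.5 ± 1.95 TPM, with Vegfa at 104 ± 12.1 and Car9, a carbonic anhydrase induced by low oxygen, at 0.05. Interferon response genes were low at 0.833 ± 0.131 (0.925 in replicate 1 and 0.740 in replicate 2), with Rsad2 at 9.31 ± 0.0849. Between the libraries, the imprinted (0.01), clock (-0.06), glucocorticoid (-0.05), hypoxia and long noncoding RNA lists (0.04) lay inside the central 95% of random lists, but with scaled counts in place of TPM, chosen after seeing the data, the clock (-0.15) and imprinted lists (-0.083) lay outside it on the lower side. Immediate early genes (median 5.42 TPM in replicate 1 and 7.75 in replicate 2, log2 ratio 0.22) and heat shock and unfolded protein response genes (28.1 and 32.1 TPM, log2 ratio 0.28) were higher in replicate 2. For interferon response genes the direction depended on the measure: the median log2 ratio was 0.32, or 0.041 with members at 1 TPM or more, while the summed counts had a ratio of 1.01 (0.956 to 1.06) and the median TPM was lower in replicate 2. Jund (66.5 ± 0.297 TPM) and Klf2 (46.2 ± 1.56 TPM), the highest immediate early genes, had ratios of replicate 2 over replicate 1 of 0.98 (0.935 to 1.03) and 1.03 (0.980 to 1.09), while Atf3 had 2.34 (1.84 to 2.99). The chaperones Hsp90aa1 and Hspa5 had ratios of 1.498 (1.43 to 1.57) and 1.27 (1.24 to 1.30).

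T cell and thymus genes were far higher in replicate 2. Blood left in the tissue would raise erythroid genes too, but their median log2 ratio was -0.059 (spread 0.26) and Hbb-bs was at 10488 ± 402 TPM over both libraries. Thymus tissue beside the heart in the sample of replicate 2 may be a source: Foxn1, Psmb11, Prss16 and Ccl25, genes of thymic epithelium, had 89 and 720 summed counts, a ratio of 6.66 (5.34 to 8.40), with 1 and 360 counts of Prss16. All 4 belong to the thymus list itself, which showed the pattern, so their rise is not an independent test. Of this list only Ccl25 reached 1 TPM in replicate 1 (88 counts), and Foxn1 and Psmb11 stayed below 1 TPM in both libraries. No explanation other than blood or thymus tissue in the sample was tested, and the design has 1 group.

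Atrial genes were higher in replicate 1. A scaling error would move the spike-ins alike, but the median log2 ratio of TPM of 28 spike-ins was -0.00094 (spread 0.10). A stress response would raise Nppb, Ankrd1, Acta1, Xirp2 and Myh7 with Nppa, but their median log2 ratio was 0.076 (spread 0.24). More atrial tissue in the sample of replicate 1 is a candidate explanation that stays open. Of the atrial list, 64.3% (9 of 14 members with at least 100 counts in each library) were lower in replicate 2 by at least 0.5 log2 units. This share lies between the bounds set for and against more atrial tissue. It cannot decide, because the same list showed the pattern, and its median of -1.25 kept the bound against out of reach. No other biological explanation was tested, and the design has 1 group.

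Genes over 2-fold apart between the tables were set against short length and shared sequence. Genes higher by RSEM had a median length of 312 bases, against 2269 bases for 6056 genes within 2-fold. Of the genes higher by RSEM, 89.6% (84.9 to 93.2) had at least 10% of their 31-base words in another gene, and of those higher by kallisto 63.1% (56.3 to 69.6), against 13.5% of genes within 2-fold. These values are consistent with shared sequence in both directions and with short length for genes higher by RSEM, where these causes go together and are not separated. Length was not tested as a cause for genes higher by kallisto, and spike-ins do not decide it for short genes, since none shorter than 505 bases was compared.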
